A study of Mus musculus with 16 samples.

How the data were processed

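RNA was measured in 16 livers of male C57BL/6 mice, 4 from each of 4 groups (RPN11 hepatocyte-specific knockout, RPN11 flox/flox, METTL3 hepatocyte-specific knockout and METTL3 flox/flox), kept on a 12-h light and dark cycle with free access to food. Diet, age and time of collection are not given in the sources used here. Per the submitters' processing notes, total RNA was taken up in TRIzol, ribosomal RNA was removed and libraries were made with a low-input kit. The authors trimmed reads with cutadapt 1.9.3, aligned them to mm10 with HISAT2 2.0.4, counted reads per gene with HTSeq 0.9.1 and normalized with edgeR, whose version is not given in the sources used here, nor is the strandedness of the libraries or the gene annotation.

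The deposited table holds 16 columns of counts per gene for 16973 genes, and these counts were the input here. Its 16 columns of normalized values were not used. Column abbreviations were matched to the sample titles by line, genotype and replicate number. All count columns held whole numbers, and no column repeated another. Ensembl identifiers were matched in GENCODE M21 (GRCm38), where 16804 of the 16973 were found, 849 of them under another symbol, and coordinates were taken from there, while symbols are those of the deposited table. More than 1 gene shared each of 31 symbols, and genes were tested by identifier.

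Each line was fitted alone, 4 knockout against 4 flox/flox livers, with edgeR 4.0.16 in R 4.3.3 (filterByExpr with the groups, TMM factors, robust quasi-likelihood fit and test). The difference between the knockout effects was an interaction contrast in 1 fit of all 16 livers, and the flox/flox livers of the lines were compared in a fit of those 8. Genes with Benjamini-Hochberg adjusted p under 0.05 are called past the threshold, and all tested genes of a fit form 1 family. Levels are counts scaled to library size (CPM) over library sizes TMM-scaled within each fit, except the summed brain list, which is over plain totals. Psmd14, Mettl3 and Acss3 also had an exact two-sided permutation test on log2(CPM + 0.5), whose smallest possible p with 4 against 4 is 0.0286. Genes changed the same way in both lines were counted from the separate fits and set beside the number expected from independent calls with Fisher's exact test, one-sided. Each fit of 8 livers had 6 residual degrees of freedom. Standard errors hold both counting error and spread between mice.

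In all, 40 gene lists were written from textbook knowledge before the data were examined, on lipid, glucose, amino acid, sterol and bile acid metabolism, zonation, sex bias, secretion, inflammation, stress, growth, the clock, the proteasome and N6-methyladenosine, and markers of other cells and of blood. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, 37 lists in the RPN11 line and 38 in the METTL3 line. Camera was repeated with a correlation estimated for each list, and fry was run beside it. Members were counted as higher, lower or not past the threshold over all tested genes, and again with adjustment over the list alone. List tests of the difference between the knockout effects and of the flox/flox livers were added after the data were seen.

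Genes are named by a rule set with the design. It takes Psmd14, Mettl3 and Acss3 always, the last from what is known of published work, and the 10 largest rises and falls of each knockout among called genes with complete separation of the 8 livers, a mean of at least 1 CPM and a named, non-pseudogene symbol. It adds up to 4 members of each list with the lowest p, the 10 genes shared in each direction with the smallest larger p, and the 10 smallest p of the difference. Any other gene named was chosen after its values were seen, which holds for the flox/flox comparison and for Arntl, Nr1d1 and the genes of the brain list. Some genes that the rule would name are not reported here. For a gene with no counts in one group, the fold is given as at least the value against a floor of 3 counts per library.

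The procedure was tested on simulated data, in which 100 genes were changed 2-fold and 100 genes 4-fold and 1 list was raised. In the RPN11 line 54% of 2-fold and 87% of 4-fold changes were recovered, in the METTL3 line 36% and 77%, in the difference 16% and 65% and between flox/flox groups 65% and 88%. In the same order, 8 of 149, 4 of 117, 5 of 86 and 15 of 168 calls were false. The raised list ranked 1 in each, and between flox/flox groups 1 further list passed. As regrouped livers gave up to 23 (RPN11 line) and 29 lists (METTL3 line), this sets no rate of false lists.

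The alternatives tried were RLE size factors, no filter beyond a count above 0, a mean of at least 5 CPM, DESeq2 1.42.0, voom with quality weights, the replicate number as a block, 1 fit of all 16 livers, a 2-fold size threshold and each liver left out in turn. Leaving out both replicate 4 knockouts, which hold transcripts of a brain list of 48 genes, was chosen after seeing the data. Other splits of the livers into groups of the same size were fitted, all 35 for 8 livers and 100 drawn for the difference and the overlap. After removing group means, same-number livers correlated at -0.083 to -0.022 in the RPN11 line (0 of 4 highest for their own number). In the METTL3 line they did at 0.057 to 0.18 (3 of 4), so pairing stays open there. No block was used. Counts per exon and reads were not analysed here.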

Results

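Transcripts were counted in 16 livers of male C57BL/6 mice, 4 in each of 4 groups. Each line, RPN11 or METTL3, had livers labelled hepatocyte-specific knockout and flox/flox livers. RPN11 is the proteasome's deubiquitylating enzyme, encoded by the gene Psmd14, and METTL3 is the catalytic subunit that writes N6-methyladenosine on mRNA. The series title places the work in nonalcoholic fatty liver disease. Libraries are numbered within groups and were taken as separate mice. SDs and single-gene p-values thus cover spread between a group's 4 livers, not litters or cohorts. Fisher and camera p-values compare genes. Labelled RPN11 knockouts 1 and 3 were the closest pair of libraries (chi-square per gene 8.37, next lowest 30.2, sampling noise 1). Whether they came from separate mice was not tested.

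Total counts per liver ran from 24516234 to 28212133 in RPN11 flox/flox livers and from 20938715 to 27645935 in livers labelled RPN11 knockout. They ran from 25062848 to 29029592 in METTL3 flox/flox livers and from 15980959 to 27778135 in METTL3 knockouts. A list of 48 brain-enriched genes, written after the data were seen, summed to 1983 CPM (counts scaled to library size) in the liver labelled RPN11 knockout replicate 4 and 1719.7 CPM in METTL3 knockout replicate 4. The other 14 livers held 207 to 331 CPM, so the total count of genes in each knockout is also given without these libraries.

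The targeted genes were looked at first. Psmd14 (ENSMUSG00000026914, chromosome 2, 61711694 to 61800376) was not lower in the livers labelled RPN11 knockout. Its transcript was at 74.2 ± 10.3 CPM (SD, n = 4) against 73.8 ± 3.28 CPM (SD, n = 4) in flox/flox livers, with ranges of 63.4 to 86.5 and 70.4 to 76.9 CPM (log2 fold change 0.01, SE 0.11, edgeR adjusted p = 0.976, exact two-sided permutation p = 1). Counts summed over a whole gene also hold exons outside a deleted part, so this value checks nothing about the protein, and these livers are called "labelled RPN11 knockout" throughout. In the METTL3 line Mettl3 (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128) fell 2.45-fold, from 16.6 ± 2.19 to 6.79 ± 0.193 CPM (SD, n = 4 each), and all 4 knockout livers lay below all 4 flox/flox livers (log2 fold change -1.29, SE 0.17, edgeR adjusted p = 0.000647, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). Mettl3 was not past the threshold in the livers labelled RPN11 knockout (log2 fold change 0.33, edgeR adjusted p = 0.323), nor was Psmd14 in the METTL3 knockouts (log2 fold change -0.30, edgeR adjusted p = 0.103).

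The acyl-CoA synthetase gene Acss3 (ENSMUSG00000035948, chromosome 10, 106933517 to 107123668), set to be named in advance from what is known of published work on these enzymes and not from the labels, was lower in both lines. It was at 6.12 ± 2.33 against 14.03 ± 1.64 CPM in the RPN11 line, with all 4 labelled knockouts below all 4 controls (SD, n = 4 each, log2 fold change -1.20, SE 0.26, edgeR adjusted p = 0.028, exact two-sided permutation p = 0.0286). In the METTL3 line it was at 4.74 ± 2.27 against 10.4 ± 3.23 CPM, with overlapping groups (SD, n = 4 each, log2 fold change -1.13, SE 0.34, edgeR adjusted p = 0.0276, exact two-sided permutation p = 0.0571). The effects in the lines did not differ past the threshold (log2 difference -0.08, edgeR adjusted p = 0.938). Leaving out flox/flox liver 1, 2, 3 or 4 or labelled knockout 2, or 1 fit of all 16 livers, ended the Acss3 call in the RPN11 line. Leaving out flox/flox liver 2, 3 or 4 or knockout 3 or 4, or voom with quality weights, ended it in the METTL3 line, with adjusted p over all alternatives from 0.00117 to 0.0988 and from 0.0092 to 0.0909.

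**Figure D1:**
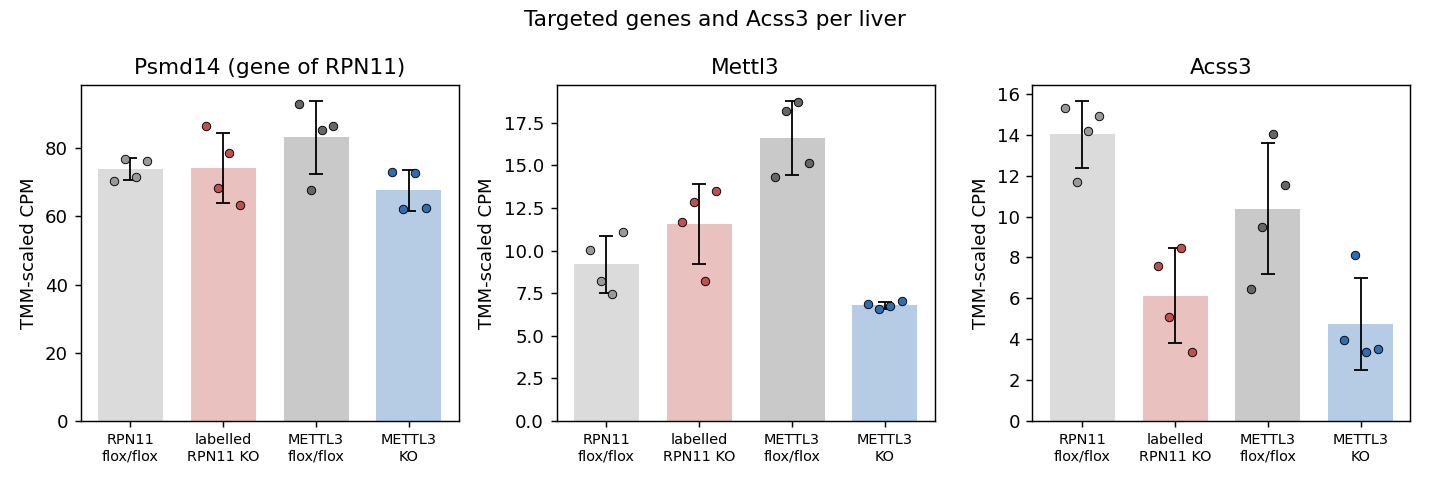
CPM of Psmd14, Mettl3 and Acss3 in each of the 16 livers, with the mean and SD of each group of 4. Psmd14 spans 63.4 to 86.5 CPM in livers labelled RPN11 knockout and 70.4 to 76.9 CPM in their controls, while Mettl3 falls from 16.6 to 6.79 CPM in the METTL3 line.

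The first comparison asks which transcripts differ between livers labelled RPN11 knockout and their flox/flox controls. Interferon-response transcripts were higher in the livers so labelled, a label that the Psmd14 counts did not bear out. Lists of fatty acid synthesis, cholesterol synthesis and fatty acid oxidation were lower with camera's preset correlation, and not past the threshold with an estimated one (adjusted p = 0.0640, 0.219 and 0.219). Most tested members of the cholesterol and oxidation lists were not called. With the preset correlation, the synthesis and oxidation lists were also higher in RPN11 than in METTL3 flox/flox livers. Usp18 (ENSMUSG00000030107), which removes the interferon-induced modifier ISG15 from proteins, was 5.31-fold higher (23.2 ± 1.60 against 4.37 ± 0.661 CPM, log2 fold change 2.41, SE 0.15, adjusted p = 4.35e-05). Srebf1 (ENSMUSG00000020538), the gene of the transcription factor that drives fatty acid synthesis, was 2.73-fold lower (34.8 ± 2.89 against 94.9 ± 12.9 CPM, log2 fold change -1.45, SE 0.12, adjusted p = 0.000413). Levels are mean ± SD over 4 livers, knockout first, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

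The interferon response was the list with the lowest p: of 27 tested members, 17 were higher, 0 lower and 10 not past the threshold. With adjustment over the list alone, 21 were higher and 0 lower. Ifi44 (ENSMUSG00000028037) was 3.804-fold higher (23.2 ± 4.72 against 6.10 ± 1.55 CPM, log2 fold change 1.93, SE 0.21, adjusted p = 0.00194). Irf7 (ENSMUSG00000025498), a transcription factor of interferon induction, was 2.77-fold higher (adjusted p = 0.00194), and Ifi27 (ENSMUSG00000064215) was 2.73-fold higher (adjusted p = 0.000797). The list passed limma's camera test (adjusted p = 4.92e-29) and was the 1 of 37 tested lists in this line that also passed with an estimated correlation (adjusted p = 0.00305). Without replicate 4, which holds the brain transcripts, 19 higher members were called and the adjusted p with an estimated correlation was 0.0131. With camera's preset correlation 20 lists passed, 9 of them higher and 11 lower.

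Genes of fatty acid and sterol synthesis that were called were mostly lower. In lipogenesis, of 23 tested members, 1 was higher, 11 lower and 11 not past the threshold. On adjustment within the list alone, 1 was higher and 17 lower (camera adjusted p = 1.74e-17, adjusted p = 0.0640 with an estimated correlation). The fatty acid synthase gene Fasn (ENSMUSG00000025153) was 2.40-fold lower (93.8 ± 14.01 against 225 ± 62.9 CPM, log2 fold change -1.26, SE 0.19, adjusted p = 0.00833). Mid1ip1 (ENSMUSG00000008035), whose product promotes acetyl-CoA carboxylase assembly, was 2.06-fold lower and Acss2 (ENSMUSG00000027605), the cytosolic acetyl-CoA synthetase, was 1.78-fold lower (adjusted p = 0.00601 and 0.00977). In cholesterol synthesis, of 23 tested members, 0 were higher, 8 lower and 15 not past the threshold. Over the list alone, 0 were higher and 13 lower (camera adjusted p = 5.02e-10, adjusted p = 0.219 with an estimated correlation). The squalene synthase gene Fdft1 (ENSMUSG00000021273) was 1.94-fold lower (45.0 ± 3.97 against 87.5 ± 17.9 CPM, log2 fold change -0.96, SE 0.14, adjusted p = 0.00821). Without replicate 4, 1 higher and 14 lower lipogenesis members and 8 lower cholesterol synthesis members were called.

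Called genes that burn and store fat were lower as well. In the list of fatty acid oxidation and PPAR alpha targets, of 27 tested members, 0 were higher, 9 lower and 18 not past the threshold. When adjusted over the list alone, 0 were higher and 18 lower (camera adjusted p = 5.15e-14, adjusted p = 0.219 with an estimated correlation). Hadh (ENSMUSG00000027984), a mitochondrial oxidation enzyme, was 1.73-fold lower (272 ± 48.4 against 470.2 ± 37.0 CPM) and the pantetheinase gene Vnn1 (ENSMUSG00000037440) was 2.32-fold lower (adjusted p = 0.0160 and 0.00339). In lipid droplets and fatty acid uptake, of 24 tested members, 0 were higher, 3 lower and 21 not past the threshold. By adjustment within the list, 0 were higher and 8 lower (camera adjusted p = 0.000211, adjusted p = 0.158 with an estimated correlation). The droplet coat gene Plin2 (ENSMUSG00000028494) was 1.66-fold lower (275 ± 22.8 against 456 ± 48.3 CPM, log2 fold change -0.73, SE 0.12, adjusted p = 0.0117), and G0s2 (ENSMUSG00000009633), an inhibitor of triglyceride lipolysis, was 2.26-fold lower (adjusted p = 0.0166). Without replicate 4, 13 lower oxidation members and 5 lower droplet members were called. In acyl-CoA synthetases and propionate metabolism, of 21 tested members, 0 were higher, 4 lower and 17 not past the threshold. Adjusted over the list alone, 1 was higher and 8 lower (camera adjusted p = 0.000241, adjusted p = 0.390 with an estimated correlation), and the 4 called were Acss2, Acss3, Acsl5 (ENSMUSG00000024981) and Bckdha (ENSMUSG00000060376). In lipoproteins and cholesterol export, of 18 tested members, 0 were higher, 2 lower and 16 not past the threshold. With adjustment over the list alone, 1 was higher and 2 lower (camera adjusted p = 0.00341, adjusted p = 0.390 with an estimated correlation), and both called genes, the hepatic lipase gene Lipc (ENSMUSG00000032207) and Pltp (ENSMUSG00000017754), were lower.

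Called sex-biased genes moved in the male direction. Among male-biased genes, of 18 tested members, 6 were higher, 0 lower and 12 not past the threshold. On adjustment within the list alone, 9 were higher and 0 lower (camera adjusted p = 3.70e-10, adjusted p = 0.288 with an estimated correlation). Cyp4a12b (ENSMUSG00000078597) was 4.83-fold higher (96.6 ± 15.1 against 20.0 ± 6.99 CPM, log2 fold change 2.27, SE 0.24, adjusted p = 0.00339), Selenbp2 (ENSMUSG00000068877) was 9.77-fold higher (adjusted p = 0.0299) and the transcriptional repressor gene Bcl6 (ENSMUSG00000022508) was 2.54-fold higher (adjusted p = 0.00997). Among female-biased genes, of 14 tested members, 0 were higher, 1 lower and 13 not past the threshold. Over the list alone, 0 were higher and 2 lower (camera adjusted p = 0.00675, adjusted p = 0.390 with an estimated correlation). The 1 called was Hao2 (ENSMUSG00000027870), which was 5.22-fold lower (adjusted p = 0.0169). Without replicate 4, 4 higher male-biased members were called.

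Macrophage markers were the cell-type list that passed with the preset correlation, and matrix, cytokine and fetal liver lists passed too, with few genes called singly, in a group whose replicate 4 held the brain transcripts. For macrophages and Kupffer cells, of 23 tested members, 1 was higher, 0 lower and 22 not past the threshold. When adjusted over the list alone, 4 were higher and 0 lower (camera adjusted p = 0.000169, adjusted p = 0.390 with an estimated correlation), and the gene called was Mpeg1 (ENSMUSG00000046805) (143 ± 24.9 against 69.6 ± 17.2 CPM, log2 fold change 1.03, SE 0.19, adjusted p = 0.0178). For extracellular matrix, of 25 tested members, 1 was higher, 0 lower and 24 not past the threshold. By adjustment within the list, 1 was higher and 0 lower (camera adjusted p = 0.00674, adjusted p = 0.543 with an estimated correlation), and the gene called was the matrix proteoglycan gene Lum (ENSMUSG00000036446) (log2 fold change 0.72, SE 0.16, adjusted p = 0.0310). For inflammatory cytokines, of 17 tested members, 0 were higher, 0 lower and 17 not past the threshold. Adjusted over the list alone, 0 were higher and 0 lower (camera adjusted p = 0.0133, adjusted p = 0.390 with an estimated correlation). For fetal liver and tumour-associated genes, of 10 tested members, 0 were higher, 0 lower and 10 not past the threshold. With adjustment over the list alone, 3 were higher and 0 lower (camera adjusted p = 0.00520, adjusted p = 0.390 with an estimated correlation), and without replicate 4 that list no longer passed camera (adjusted p = 0.0540). Lymphocyte markers did not pass (camera adjusted p = 0.0653, 1 higher and 0 lower of 5), and the 1 gene called was the leukocyte gene Ptprc (ENSMUSG00000026395) (log2 fold change 1.28, SE 0.26, adjusted p = 0.0268), at 55.8 CPM in replicate 4 and 24.1 to 27.7 CPM in the other 3 knockouts. Without replicate 4 the lymphocyte list passed camera with 8 tested members (adjusted p = 0.00846, adjusted p = 0.343 with an estimated correlation), and 2 higher macrophage and 3 higher matrix members were called.

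The complexes that the targeted genes belong to did not pass. Of 36 tested proteasome subunit genes, 0 were higher and 0 lower, with no call under edgeR's quasi-likelihood test (camera adjusted p = 0.107). Without replicate 4, 3 higher proteasome genes were called and the list passed camera (adjusted p = 0.0221, adjusted p = 0.525 with an estimated correlation). Of 18 tested genes of the N6-methyladenosine machinery, 2 were higher and 0 lower (camera adjusted p = 0.0959), and those were Ythdc1 (ENSMUSG00000035851) (log2 fold change 0.56, SE 0.14, adjusted p = 0.0409) and Hnrnpa2b1 (ENSMUSG00000004980) (log2 fold change 0.52, SE 0.13, adjusted p = 0.0434).

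By size of change, the 10 largest rises were Fbxo2, Gpr22, Ptprn, Moxd1, Gpr141, Bcl2a1d, Sirpb1c, Il3ra, Klhl11 and Selenbp2. Fbxo2 (ENSMUSG00000041556) had 220 counts over the 4 labelled knockouts (2.11 ± 0.0897 CPM, SD, n = 4) and 1 count over the 4 controls (adjusted p = 0.00194). Moxd1 (ENSMUSG00000020000) was at 1.998 ± 1.28 against 0.0811 ± 0.0363 CPM (adjusted p = 0.0107). In 6 of the 10, replicate 4 lay far above the other knockouts, as for Gpr22 (ENSMUSG00000044067) at 9.75 CPM against 0.436 to 0.961 CPM, and without that liver the calls of Bcl2a1d (ENSMUSG00000096581) and Sirpb1c (ENSMUSG00000074677) ended. The 10 largest falls were Slc22a26, Cyp2a22, Hao2, Sema5b, Lamb3, Slc22a29, Dclk3, Tlr12, Aqp8 and Ugt1a5. Dclk3 (ENSMUSG00000032500) was 2.97-fold lower (4.01 ± 0.313 against 11.9 ± 1.47 CPM, log2 fold change -1.57, SE 0.18, adjusted p = 0.00239) and Sema5b (ENSMUSG00000052133) was 4.46-fold lower (adjusted p = 0.0152). Calls ended in 9, 6, 9 and 8 of these rises without flox/flox 1 to 4 and in 2, 6, 2 and 2 without labelled knockouts 1 to 4 (highest adjusted p 0.149). In these falls they ended in 9, 4, 9 and 9 and in 4, 6, 3 and 1 (highest adjusted p 0.139). Slc22a, Cyp2, Ugt1a, Cyp4a, Selenbp, Bcl2a1, Sirpb1 and Acaa1 genes have close relatives or shared exons, so how their counts split is uncertain.

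Over all 12108 tested genes, 241 were higher and 342 lower past the threshold, and 3032 had an unadjusted p under 0.05. In 580 of these 583 genes all 4 labelled knockouts lay on the same side of all 4 controls, an order that chance gives in 2.86% of genes and that 2201 of all tested genes showed. Every gene named for this comparison as past the threshold is among the 580 except Pltp. Leaving out 1 liver moved the counts by over 1.5 times, to 37 higher and 23 lower without flox/flox 1, 124 and 141 without flox/flox 2, 41 and 18 without flox/flox 3, 51 and 33 without flox/flox 4, and 87 and 92 without labelled knockout 2. Without labelled knockout 4 the higher genes moved by over 1.5 times, to 447, and the lower genes by less, to 494, with 230 of the 241 and 333 of the 342 genes kept. Of 50 genes given as list examples, the calls of 34, 17, 35 and 31 ended without flox/flox 1, 2, 3 and 4, and those of 8, 27, 7 and 0 without labelled knockouts 1, 2, 3 and 4 (highest adjusted p 0.156), while Usp18, Ifi27, Irf7, Ifi44, Srebf1, Fasn, Fdft1, Mid1ip1, Cyp4a12b and Vnn1 kept theirs in all of these.

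**Figure D2:**
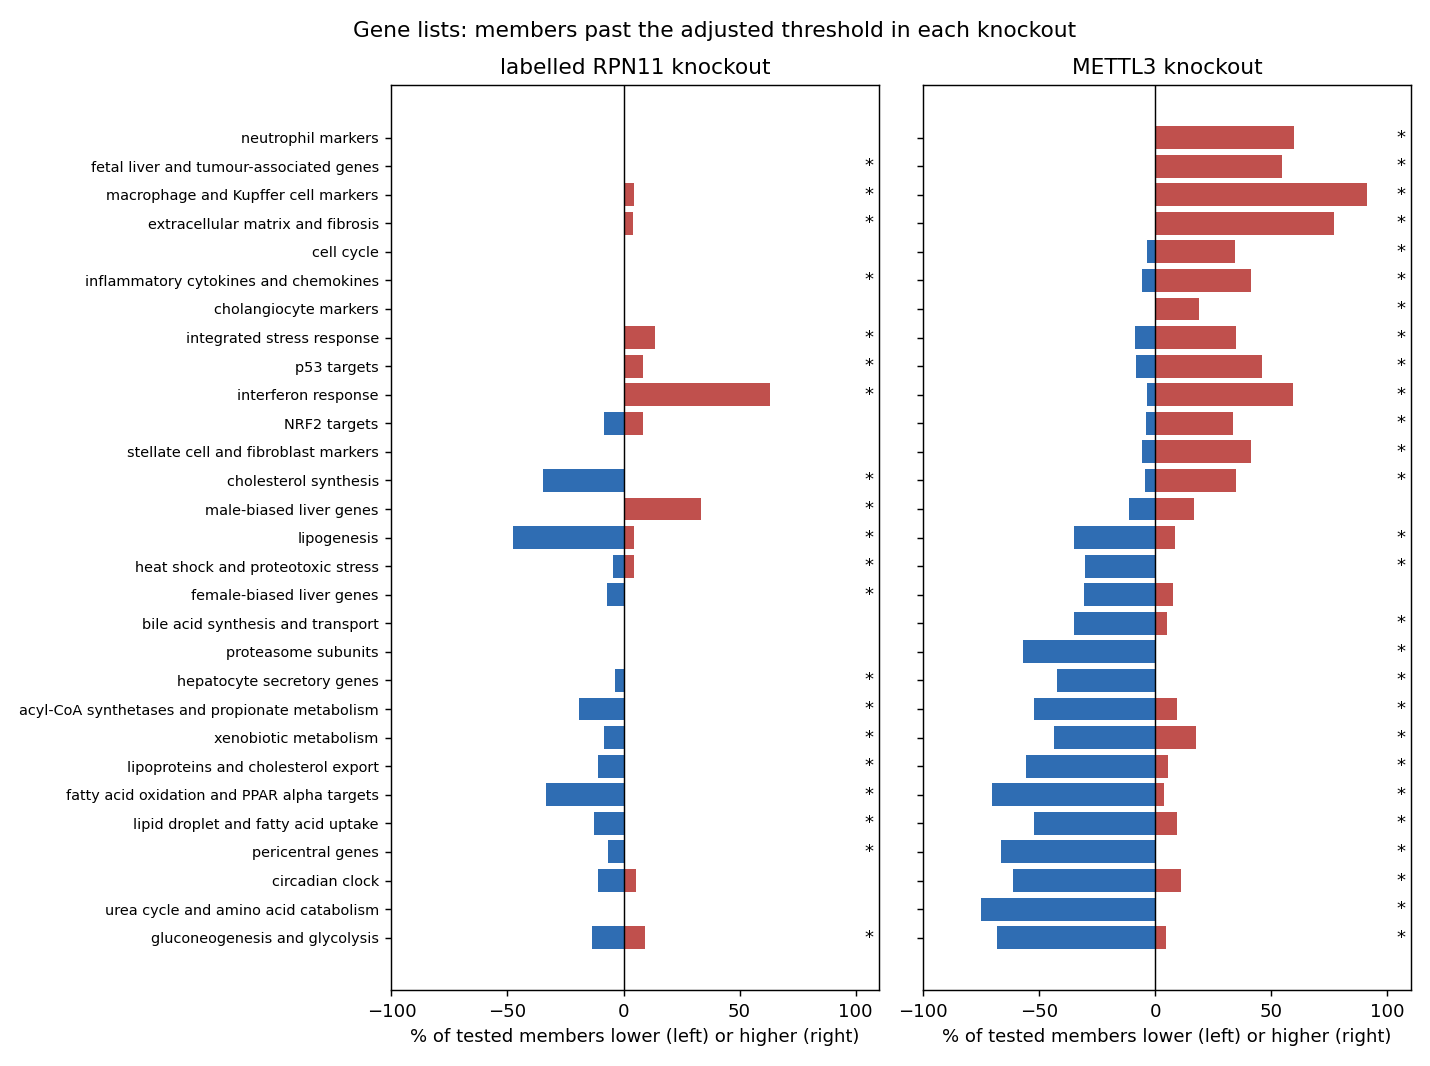
Percentage of tested members of each gene list that were lower or higher past the threshold in livers labelled RPN11 knockout and in METTL3 knockouts, with an asterisk where camera passed with its preset correlation. Of 27 tested interferon genes, 17 are higher in the RPN11 line and 16 in the METTL3 line.

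The second comparison asks what changes in liver when METTL3 is deleted in hepatocytes. Many genes of hepatocyte metabolism (glucose, urea synthesis, fat oxidation, lipoproteins) fell, clock genes changed in both directions, and many macrophage, matrix and interferon genes rose. Of these lists the clock alone passed with an estimated correlation, where the others had adjusted p from 0.180 to 0.301. Usp2 (ENSMUSG00000032010), a deubiquitylase gene with a strong daily rhythm in liver, fell 30.2-fold (1.91 ± 0.326 against 57.5 ± 12.2 CPM, log2 fold change -4.91, SE 0.21, adjusted p = 4.45e-07). Asl (ENSMUSG00000025533), the urea cycle's argininosuccinate lyase gene, fell 5.66-fold (117 ± 41.6 against 659.9 ± 113 CPM, log2 fold change -2.50, SE 0.26, adjusted p = 0.000189), while the type I collagen gene Col1a1 (ENSMUSG00000001506) rose 9.31-fold (28.1 ± 12.1 against 3.03 ± 1.10 CPM, log2 fold change 3.22, SE 0.40, adjusted p = 0.000647).

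Clock genes changed in both directions: of 18 tested members, 2 were higher, 11 lower and 5 not past the threshold. On adjustment within the list alone, 3 were higher and 11 lower. The output genes Dbp (ENSMUSG00000059824) (25.6-fold lower, 2.32 ± 0.995 against 59.4 ± 23.0 CPM, log2 fold change -4.68, SE 0.42, adjusted p = 0.00028) and Tef (ENSMUSG00000022389) (5.55-fold lower, adjusted p = 0.000469) fell. The Period gene Per3 (ENSMUSG00000028957) fell as well (9.81-fold lower, adjusted p = 6.24e-05). Both genes that rose belong to the positive arm of the clock. They were Arntl (log2 fold change 1.91, SE 0.33, adjusted p = 0.00233) and Npas2 (ENSMUSG00000026077) (35.7-fold higher, 12.9 ± 5.94 against 0.361 ± 0.306 CPM, log2 fold change 5.16, SE 0.61, adjusted p = 0.000456). Nr1d1, which represses Arntl, was not past the threshold (log2 fold change -0.48, SE 0.49, adjusted p = 0.487). The clock list passed camera (adjusted p = 2.29e-10) and was the 1 of 38 tested lists in this line that passed with an estimated correlation (adjusted p = 0.0139). Without replicate 4, which holds the brain transcripts, 2 higher and 11 lower clock genes were called, with adjusted p = 0.0303 with an estimated correlation. With the preset correlation 27 lists passed, 13 higher and 14 lower.

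**Figure D3:**
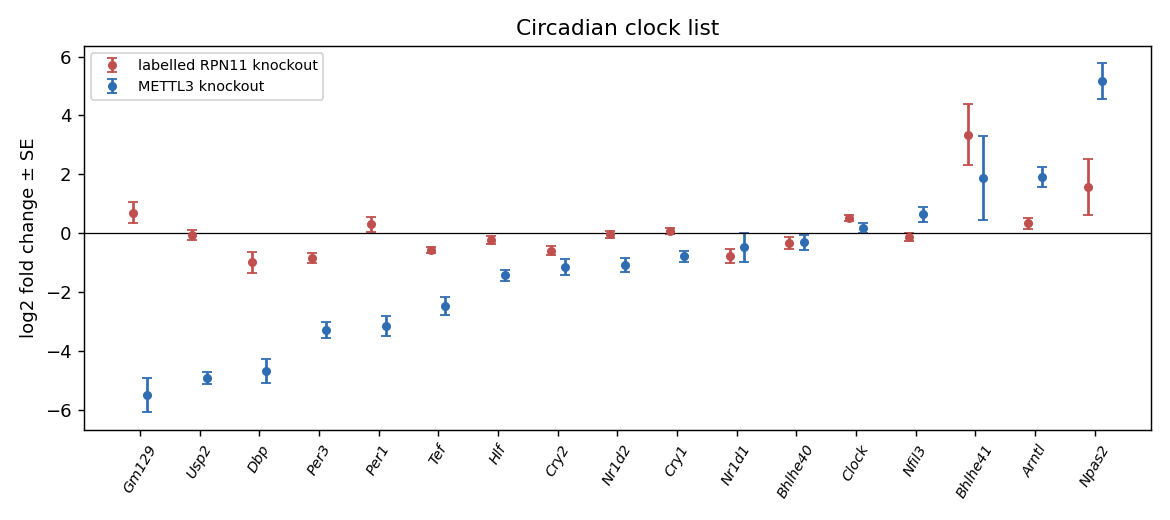
Log2 fold change with its standard error for tested clock genes in livers labelled RPN11 knockout and in METTL3 knockouts, each against its own flox/flox controls. In the METTL3 line, genes past the threshold include Usp2 at -4.91 and Npas2 at 5.16.

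Most tested genes of glucose and nitrogen metabolism fell. In gluconeogenesis and glycolysis, of 22 tested members, 1 was higher, 15 lower and 6 not past the threshold. Over the list alone, 1 was higher and 17 lower (camera adjusted p = 1.51e-11, adjusted p = 0.235 with an estimated correlation). The glucose-6-phosphate transporter gene Slc37a4 (ENSMUSG00000032114) fell 4.02-fold (41.7 ± 9.03 against 168 ± 16.05 CPM, log2 fold change -2.01, SE 0.16, adjusted p = 6.24e-05), Pfkfb1 (ENSMUSG00000025271) fell 3.76-fold (adjusted p = 6.24e-05) and the serine dehydratase gene Sds (ENSMUSG00000029597) fell 3.48-fold (adjusted p = 0.000194). In the urea cycle and amino acid catabolism, of 24 tested members, 0 were higher, 18 lower and 6 not past the threshold. When adjusted over the list alone, 0 were higher and 18 lower (camera adjusted p = 1.21e-10, adjusted p = 0.301 with an estimated correlation). Ass1 (ENSMUSG00000076441) fell 3.18-fold (983 ± 247 against 3122 ± 532 CPM, log2 fold change -1.67, SE 0.23, adjusted p = 0.000667) and the arginase gene Arg1 (ENSMUSG00000019987) fell 2.43-fold (adjusted p = 0.00170). Without replicate 4, 12 lower glucose genes and 17 lower urea and amino acid genes were called.

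Lipid genes that were called mostly fell. In fatty acid oxidation and PPAR alpha targets, of 27 tested members, 1 was higher, 19 lower and 7 not past the threshold. By adjustment within the list, 1 was higher and 21 lower (camera adjusted p = 2.38e-08, adjusted p = 0.301 with an estimated correlation). The carnitine carrier gene Slc25a20 (ENSMUSG00000032602) fell 2.28-fold (79.6 ± 18.9 against 182 ± 18.1 CPM, log2 fold change -1.19, SE 0.18, adjusted p = 0.00100), Hadh fell 2.36-fold (adjusted p = 0.00113) and Acadl (ENSMUSG00000026003) fell 2.01-fold (adjusted p = 0.00175). In lipid droplets and fatty acid uptake, of 21 tested members, 2 were higher, 11 lower and 8 not past the threshold. Adjusted over the list alone, 2 were higher and 13 lower (camera adjusted p = 0.000367, adjusted p = 0.301 with an estimated correlation). Plin4 (ENSMUSG00000002831) fell 10.8-fold (0.730 ± 0.170 against 7.99 ± 4.41 CPM, log2 fold change -3.44, SE 0.42, adjusted p = 0.000434), Mgll (ENSMUSG00000033174) fell 3.30-fold (adjusted p = 9.90e-05) and the lipoprotein lipase gene Lpl (ENSMUSG00000015568), low in adult hepatocytes, rose 7.64-fold (adjusted p = 0.000141). In lipoproteins, of 18 tested members, 1 was higher, 10 lower and 7 not past the threshold. With adjustment over the list alone, 1 was higher and 10 lower (camera adjusted p = 3.44e-06, adjusted p = 0.301 with an estimated correlation), with Apoc3 (ENSMUSG00000032081) falling 2.57-fold and Apoa4 (ENSMUSG00000032080) 2.67-fold (adjusted p = 0.000792 and 0.00204). In lipogenesis, of 23 tested members, 2 were higher, 8 lower and 13 not past the threshold. On adjustment within the list alone, 2 were higher and 8 lower (camera adjusted p = 0.0137, adjusted p = 0.301 with an estimated correlation). Lpin1 (ENSMUSG00000020593) fell 4.29-fold (adjusted p = 0.000194), and the desaturase genes Fads2 (ENSMUSG00000024665) and Fads1 (ENSMUSG00000010663) fell 2.93-fold and 2.29-fold (adjusted p = 0.000646 and 0.00172). Without replicate 4, 1 higher and 18 lower oxidation genes and 1 higher and 12 lower droplet genes were called, and 1 higher and 10 lower lipoprotein genes and 2 higher and 8 lower lipogenesis genes.

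In bile acid synthesis and transport, of 20 tested members, 1 was higher, 7 lower and 12 not past the threshold. Over the list alone, 1 was higher and 7 lower (camera adjusted p = 0.0180, adjusted p = 0.444 with an estimated correlation). Cyp7a1 (ENSMUSG00000028240), the rate-limiting enzyme of bile acid synthesis, fell 3.32-fold (79.6 ± 29.1 against 264 ± 22.0 CPM, log2 fold change -1.73, SE 0.23, adjusted p = 0.000647), and the bile acid receptor gene Nr1h4 (ENSMUSG00000047638) and the uptake carrier gene Slc10a1 (ENSMUSG00000021135) fell 2.15-fold and 2.75-fold (adjusted p = 0.000647 and 0.00339). Without replicate 4 that list no longer passed camera (adjusted p = 0.0592). In acyl-CoA synthetases and propionate metabolism, of 21 tested members, 2 were higher, 11 lower and 8 not past the threshold. When adjusted over the list alone, 2 were higher and 11 lower (camera adjusted p = 0.00732, adjusted p = 0.349 with an estimated correlation). Acsl4 (ENSMUSG00000031278) rose 6.24-fold (adjusted p = 0.000548) and Acsl3 (ENSMUSG00000032883) rose 2.25-fold (adjusted p = 0.000456).

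Many transcripts typical of other liver cells rose, in a group whose replicate 4 held 1719.7 CPM of brain-list transcripts against 244 to 291 CPM in the other 3 knockouts. For macrophages and Kupffer cells, of 23 tested members, 21 were higher, 0 lower and 2 not past the threshold. By adjustment within the list, 23 were higher and 0 lower (camera adjusted p = 7.50e-14, adjusted p = 0.301 with an estimated correlation). Cd5l (ENSMUSG00000015854) rose 2.94-fold (132 ± 17.5 against 44.9 ± 7.46 CPM, log2 fold change 1.55, SE 0.15, adjusted p = 0.000172), Vsig4 (ENSMUSG00000044206) 2.61-fold and the complement gene C1qc (ENSMUSG00000036896) 2.31-fold (adjusted p = 0.000324 and 0.000332). For extracellular matrix and fibrosis, of 26 tested members, 20 were higher, 0 lower and 6 not past the threshold. Adjusted over the list alone, 22 were higher and 0 lower (camera adjusted p = 8.55e-13, adjusted p = 0.180 with an estimated correlation). Fbn1 (ENSMUSG00000027204) rose 5.596-fold and Col6a3 (ENSMUSG00000048126) 3.53-fold (adjusted p = 0.000647 and 0.00028). Without replicate 4, 19 higher macrophage genes and 20 higher matrix genes were called. For stellate cells and fibroblasts, of 17 tested members, 7 were higher, 1 lower and 9 not past the threshold. With adjustment over the list alone, 7 were higher and 1 lower (camera adjusted p = 0.0129, adjusted p = 0.301 with an estimated correlation), with Pdgfrb (ENSMUSG00000024620) 2.37-fold and Lrat (ENSMUSG00000028003) 2.79-fold higher (adjusted p = 0.00078 and 0.00325). For neutrophils, of 5 tested members, 3 were higher, 0 lower and 2 not past the threshold. On adjustment within the list alone, 4 were higher and 0 lower (camera adjusted p = 0.0129, adjusted p = 0.301 with an estimated correlation), with S100a9 (ENSMUSG00000056071) at 5.66 ± 3.82 against 0.782 ± 0.503 CPM (adjusted p = 0.0140, and 0.0538 without knockout 3).

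Most called interferon, cytokine and growth genes rose as well. For the interferon response, of 27 tested members, 16 were higher, 1 lower and 10 not past the threshold. Over the list alone, 18 were higher and 1 lower (camera adjusted p = 0.000109, adjusted p = 0.301 with an estimated correlation). Oasl1 (ENSMUSG00000041827) rose 5.95-fold (31.3 ± 14.4 against 5.25 ± 1.04 CPM, log2 fold change 2.57, SE 0.36, adjusted p = 0.00113), Ifit2 (ENSMUSG00000045932) 2.47-fold and Rsad2 (ENSMUSG00000020641) 2.07-fold (adjusted p = 0.00181 and 0.00242). For inflammatory cytokines, of 17 tested members, 7 were higher, 1 lower and 9 not past the threshold. When adjusted over the list alone, 10 were higher and 1 lower (camera adjusted p = 0.00595, adjusted p = 0.357 with an estimated correlation), with Icam1 (ENSMUSG00000037405) 2.53-fold and Ccl9 (ENSMUSG00000019122) 2.44-fold higher (adjusted p = 0.00353 and 0.00481). For the cell cycle, of 29 tested members, 10 were higher, 1 lower and 18 not past the threshold. By adjustment within the list, 13 were higher and 2 lower (camera adjusted p = 0.000627, adjusted p = 0.444 with an estimated correlation), and Ccnd1 (ENSMUSG00000070348), the cyclin D1 gene, rose 5.08-fold (62.3 ± 18.7 against 12.2 ± 1.46 CPM, log2 fold change 2.35, SE 0.22, adjusted p = 0.00014). For fetal liver and tumour-associated genes, of 11 tested members, 6 were higher, 0 lower and 5 not past the threshold. Adjusted over the list alone, 6 were higher and 0 lower (camera adjusted p = 0.000104, adjusted p = 0.301 with an estimated correlation), with Sox9 (ENSMUSG00000000567) 4.82-fold and Golm1 (ENSMUSG00000021556) 8.70-fold higher (adjusted p = 0.000123 and 0.00162). Without replicate 4, 16 higher interferon genes and 6 higher and 1 lower cell cycle genes were called.

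Many proteasome subunit genes fell in METTL3 knockouts: of 35 tested members, 0 were higher, 20 lower and 15 not past the threshold. With adjustment over the list alone, 0 were higher and 22 lower (camera adjusted p = 2.83e-06, adjusted p = 0.316 with an estimated correlation). Psmb1 (ENSMUSG00000014769) fell 1.64-fold (71.8 ± 6.36 against 118 ± 7.94 CPM, log2 fold change -0.71, SE 0.12, adjusted p = 0.00181), Psmb4 (ENSMUSG00000005779) 1.71-fold and Psmb2 (ENSMUSG00000028837) 1.57-fold (adjusted p = 0.00201 and 0.00217), and without replicate 4 the count was 18 lower. The N6-methyladenosine machinery other than Mettl3 did not pass (4 higher and 1 lower of 18, 4 and 1 adjusted over the list alone, camera adjusted p = 0.0746, adjusted p = 0.444 with an estimated correlation). The reader gene Ythdf2 (ENSMUSG00000040025) rose 2.02-fold (adjusted p = 0.00358) and Ythdf1 (ENSMUSG00000038848) 1.57-fold (adjusted p = 0.0131). Without replicate 4, 3 higher genes of that list were called.

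The 10 largest rises were Tmc5, Vmn2r3, Gldn, Moxd1, Cib3, Dnah5, Elf3, Dhrs9, Tuba8 and Npas2. Tmc5 (ENSMUSG00000030650) had 350 counts over the 4 knockouts (3.33 ± 3.12 CPM, SD, n = 4) and 0 over the 4 controls, at least 26.0-fold higher against a floor of 3 counts per library (adjusted p = 0.00313). Dhrs9 (ENSMUSG00000027068), a retinol dehydrogenase gene, rose 46.0-fold (24.8 ± 8.59 against 0.537 ± 0.126 CPM, log2 fold change 5.52, SE 0.35, adjusted p = 9.29e-06), and the epithelial transcription factor gene Elf3 (ENSMUSG00000003051) was at 18.99 ± 13.0 against 0.341 ± 0.406 CPM (adjusted p = 0.00941). The 10 largest falls were Cyp2b9, Mfsd2a, Usp2, Lmod2, Dbp, Sema5b, Pcp4l1, Acot3, Wfdc2 and Cyp17a1. Mfsd2a (ENSMUSG00000028655), a lysophosphatidylcholine transporter gene, fell 48.0-fold (3.20 ± 0.909 against 153 ± 46.1 CPM, log2 fold change -5.58, SE 0.30, adjusted p = 5.11e-06) and Cyp2b9 (ENSMUSG00000040660) fell 85.2-fold (1.07 ± 0.627 against 92.4 ± 66.6 CPM, log2 fold change -6.41, SE 0.70, adjusted p = 0.00103). Cyp2b, Acot, Ifit, Oas, Vmn2r, Gstm and Cyp3a genes have close relatives, so how their counts split is uncertain.

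Over 12450 tested genes, 1893 were higher and 1906 lower past the threshold, and 5323 had an unadjusted p under 0.05. In 3239 of these 3799 genes all 4 knockouts lay on the same side of all 4 controls (2.86% by chance, 3936 of all tested genes), including every gene named for this comparison as past the threshold except Acss3. Without replicate 4, the counts were 1520 and 1538, with 1453 of the 1893 higher and 1500 of the 1906 lower genes kept. Leaving out any 1 of the 8 livers left each count within 1.5 times, 1383 to 2451 higher and 1341 to 2481 lower, and ended none of the 20 calls of largest rises and falls.

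The third comparison asks which genes changed the same way in both lines, as far as the label of the RPN11 knockouts holds. Interferon-induced genes were among the named shared rises and genes of fatty acid handling among the named shared falls, and no list was tested on the shared genes. Rnf213 (ENSMUSG00000070327), an interferon-induced ubiquitin ligase gene, rose 1.83-fold (116 ± 7.47 against 63.2 ± 6.83 CPM, log2 fold change 0.88, SE 0.11, adjusted p = 0.00339) in livers labelled RPN11 knockout and 1.84-fold (134 ± 21.4 against 72.8 ± 7.25 CPM, log2 fold change 0.88, SE 0.15, adjusted p = 0.00180) in METTL3 knockouts. Vnn1 fell 2.32-fold (62.1 ± 6.66 against 144 ± 27.3 CPM) and 2.65-fold (43.3 ± 8.69 against 115 ± 23.2 CPM, log2 fold change -1.40, SE 0.18, adjusted p = 0.00054), and Fads2, the delta-6 desaturase gene, fell 2.37-fold (290.2 ± 86.8 against 688 ± 60.7 CPM, log2 fold change -1.25, SE 0.20, adjusted p = 0.0114) and 2.93-fold (124 ± 33.4 against 364 ± 66.9 CPM).

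Of 11938 genes tested in both lines, 68 were higher in both against 36.0 expected from independent lists (Fisher's exact test, one-sided, p = 6.27e-08). A further 152 were lower in both against 54.6 expected (Fisher's exact test, one-sided, p = 9.62e-37). In opposite directions 22 genes were higher in the RPN11 line and lower in the METTL3 line (37.4 expected) and 16 the reverse (52.7 expected). The lines share no control livers. By the smallest larger p, the shared rises were Rnf213, Btg3, Filip1l, Rsad2, Sla, Moxd1, Ifit2, Mpeg1, Trim30a and Marcks, and shared falls were Vnn1, Mgll, Epha1, Fads2, Paqr7, Bphl, Fam73b, Sema5b and Tef. Btg3 (ENSMUSG00000022863), an antiproliferative gene, rose 3.59-fold and 4.39-fold (adjusted p = 0.00442 and 0.00201), and Mgll, the monoacylglycerol lipase gene, fell 1.65-fold and 3.30-fold (adjusted p = 0.00728 and 9.90e-05). Over all genes tested in both, the fold changes correlated across genes (Pearson's r 0.53, Spearman's rho 0.37), and genes are not independent replicates.

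Both knockout groups hold a replicate 4 with brain transcripts, 1983 and 1719.7 CPM. Without both, 97 genes were higher and 171 lower in both lines, and across 12052 genes r was 0.26 and rho 0.22. The shared counts moved by over 1.5 times without any 1 of 7 livers of the RPN11 line, most without flox/flox 1 (17 higher against 5.37 expected by chance and 6 lower against 3.63), 3 (19 against 5.99 and 3 against 2.83) and 4 (20 against 7.37 and 10 against 5.20). Relative to chance the excess of shared lower genes was smaller there, and that of shared higher genes was larger.

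**Figure D4:**
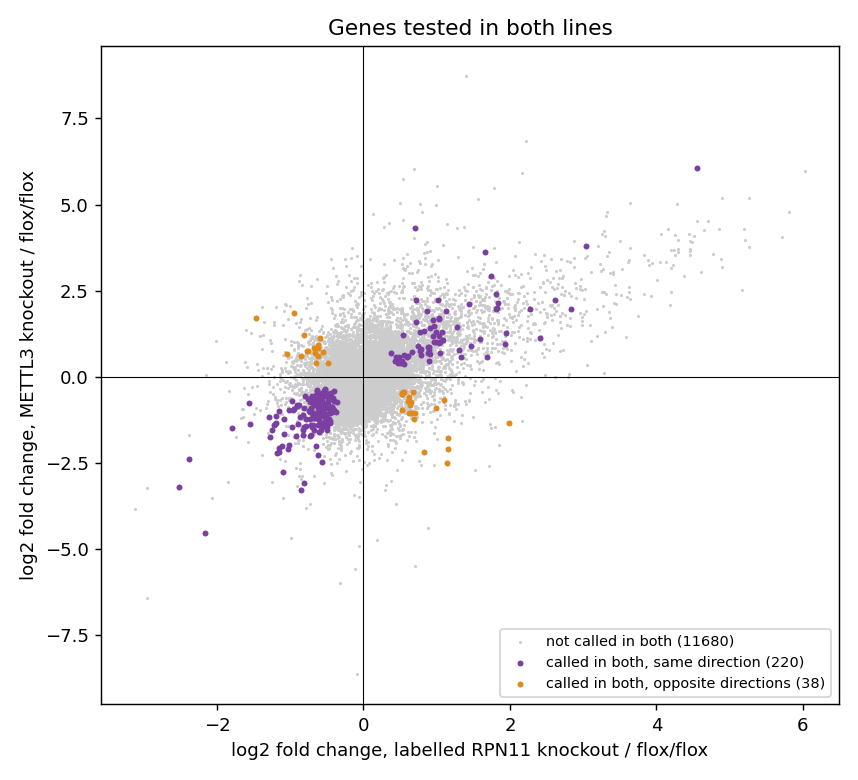
Log2 fold change of each gene tested in both lines, in livers labelled RPN11 knockout on one axis and METTL3 knockouts on the other, each against its own flox/flox controls. Genes past the threshold in the same direction in both, 68 higher and 152 lower, are marked, and r is 0.53 over all 11938 genes.

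The fourth comparison asks where the effects differ between the lines, again as far as the RPN11 labels hold. The clock list was lower in METTL3 knockouts relative to livers labelled RPN11 knockout, and passed with an estimated correlation. Urea cycle and proteasome genes fell in METTL3 knockouts with no member lower past the threshold in livers labelled RPN11 knockout, but these list differences did not pass with an estimated correlation (adjusted p = 0.374 each). Usp2 and Mfsd2a were unmoved past the threshold in livers labelled RPN11 knockout (log2 fold change -0.06 and -0.12, adjusted p = 0.852 and 0.661) and fell in METTL3 knockouts, a log2 difference of 4.84 (SE 0.28, adjusted p = 1.38e-08) and 5.45 (SE 0.33, adjusted p = 2.00e-08). Lpin1, a phosphatidate phosphatase gene, went opposite ways. Its log2 fold change was 1.15 (SE 0.19, adjusted p = 0.0131) in livers labelled RPN11 knockout and -2.10 (SE 0.22, adjusted p = 0.000194) in METTL3 knockouts. The sialyltransferase gene St6gal1 (ENSMUSG00000022885) was lower in the first (log2 fold change -0.95, adjusted p = 0.0222) and higher in the second (1.85, adjusted p = 0.000478).

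The interaction passed for 1720 of 13118 genes, 913 with the RPN11-line effect above the METTL3-line effect and 807 below, and 3658 had an unadjusted p under 0.05. Mettl3 itself differed by 1.60 (SE 0.25, adjusted p = 0.000751). Gene lists were tested for this contrast only after the data were seen. The circadian clock list (10 genes above and 1 below of 18, median log2 difference 1.10) was the 1 of 38 lists past the threshold with an estimated correlation (adjusted p = 0.000419). With the preset correlation 20 lists passed. Among them were cholesterol synthesis (1 gene above and 16 below of 23, camera adjusted p = 2.03e-10, adjusted p = 0.354 with an estimated correlation), the urea cycle (14 above and 0 below of 24, camera adjusted p = 4.48e-10, adjusted p = 0.374 with an estimated correlation) and proteasome subunits (17 above and 0 below of 36, camera adjusted p = 1.48e-08, adjusted p = 0.374 with an estimated correlation). Without both replicate 4 knockouts, 771 of the 913 and 668 of the 807 genes were kept, and the total moved by over 1.5 times without RPN11 flox/flox 1 (1095), labelled RPN11 knockout 2 (1110) or METTL3 knockout 1 (2663).

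The last comparison sets the flox/flox livers of the lines against each other, as the background on which each knockout was measured. Genes named here were chosen after their values were seen. Fads2 was at 659 ± 61.0 against 314 ± 55.4 CPM (SD, n = 4 each, log2 fold change 1.07, SE 0.12, adjusted p = 0.00176). Acaca, the acetyl-CoA carboxylase gene, was at 116 ± 8.66 against 72.6 ± 15.3 CPM (log2 fold change 0.67, adjusted p = 0.0435), and Bcl6 at 12.9 ± 2.21 against 59.9 ± 21.9 CPM (log2 fold change -2.22, adjusted p = 0.0389). Lists were tested here only after the data were seen, and lipogenesis (2 higher and 0 lower of 23, 15 and 2 adjusted over the list alone) was the 1 of 37 that passed with an estimated correlation (adjusted p = 0.0372). With the preset one 11 passed, among them macrophage markers higher (median log2 fold change 0.51, camera adjusted p = 1.99e-06, adjusted p = 0.651 with an estimated correlation) and ribosomal protein genes lower (median -0.27, camera adjusted p = 3.53e-09, adjusted p = 0.651 with an estimated correlation), with no member called in either. Fatty acid oxidation, lipid droplet and cholesterol synthesis lists were higher too (camera adjusted p = 3.83e-05, 0.00154 and 0.0227, and 0.651, 0.651 and 0.701 with an estimated correlation). Male-biased genes were lower (camera adjusted p = 0.00114, and 0.651 with an estimated correlation). In livers labelled RPN11 knockout, set against these same RPN11 controls, the lipid lists and male-biased genes moved the other way.

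In all, 29 of 11905 genes were higher and 9 lower in the RPN11 flox/flox livers, and 1962 had an unadjusted p under 0.05. All 38 had the 4 livers of one line on the same side of the 4 of the other. The count moved by over 1.5 times without RPN11 flox/flox 1 (1), 2 (13), 3 (1) or 4 (88) and without METTL3 flox/flox 1 (21), 2 (17), 3 (5) or 4 (282).

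**Figure D5:**
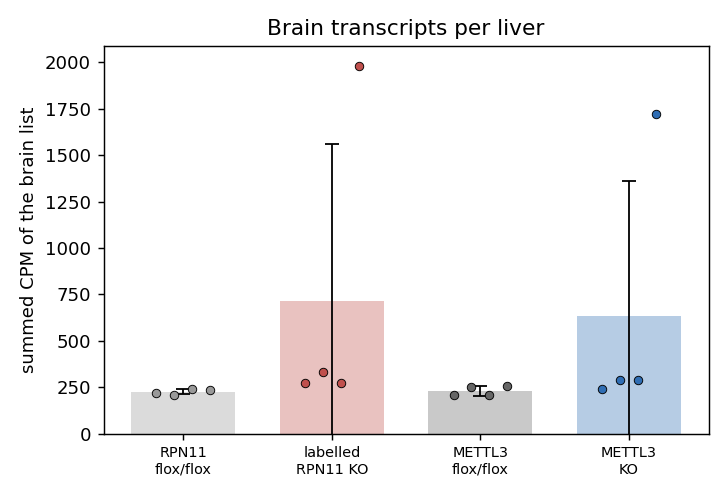
Summed CPM of the brain-enriched list in each of the 16 livers, by group, with the mean and SD of each group. The liver labelled RPN11 knockout replicate 4 holds 1983 CPM and METTL3 knockout replicate 4 holds 1719.7 CPM, and the other 14 hold 207 to 331 CPM.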

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

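Among the tests in this part, the splits of the livers (but not those for lists between flox/flox groups and in the difference) and the search for exchanged labels within the RPN11 line were set beforehand, and all other tests were chosen only after the result was seen.

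Brain transcripts in 2 livers form the first pattern. Of 39 brain-list genes averaging below 5 CPM over the other 14 livers, 38 were at least 4-fold higher in both the liver labelled RPN11 knockout replicate 4 and METTL3 knockout replicate 4 (median 24.8-fold and 21.3-fold over the other 3 of their group). Their levels in these livers correlated across genes (Pearson's r 0.968), with Camk2a at 137 and 88.2 CPM and Snap25 at 97.9 and 72.9 CPM. An effect of both knockouts was argued against, since the other 3 knockout livers had a median log2 ratio over controls of 0.11 in the METTL3 line and 0.54 in the RPN11 line. In the RPN11 line those 3 still lay above controls (272 to 331 against 211 to 240 CPM of the list) and 3 of 19 brain genes were called higher without replicate 4, so a smaller rise there stays open. The values are consistent with brain RNA in these 2 libraries, whose route (tissue, carry-over or shared handling) was not tested.

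Psmd14, which was not lower in the livers labelled RPN11 knockout, is the second pattern. Labels exchanged between the lines were argued against by Mettl3, which was not lower in that line (log2 fold change 0.33). A partial exchange of labels within the line was argued against as well, since the 2 livers nearer to the other group (labelled knockouts 1 and 3) had no partner among the controls, and without replicate 4 there were 0. An exchange of all labels would leave these values unchanged, so it was not tested. Exons outside a deleted part could still be counted, and the whole-gene value (0.00734) cannot tell. No biological explanation was tested.

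Clock genes of the METTL3 line are the third pattern. Library scaling was argued against, because 2 called genes (Arntl and Npas2) went against the other 11. RNA of another tissue in replicate 4 was argued against, because 13 of 13 calls held without that liver. Livers collected at another time of day could give such a pattern, and Nr1d1 (log2 fold change -0.48), with no collection times, cannot tell. An effect of METTL3 loss on the clock stays open as a hypothesis beside it.

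Other splits of the livers gave these results. For the 583 called genes of the RPN11 line and the 3799 of the METTL3 line, the real split was the only 1 of 35 with as many genes (highest other 0). This argues against chance, but 35 splits, of which the others mix the groups, cannot exclude it. Chance was not argued against for the 38 genes between flox/flox groups (2 of 35 splits as large, highest other 40), the 20 lists of the RPN11 line (8 of 35, highest other 23), the 27 of the METTL3 line (3 of 35, highest other 29), the 11 between flox/flox groups (11 of 35, highest other 20) or the 20 in the difference (41 of 100 draws, highest other 30). For the 220 genes shared by the lines the splits decide nothing beyond the separate calls, since any pair with 1 line regrouped had no called genes to share (1 of 100 pairs as large, highest other 0). For the 1720 genes that differ between the knockout effects, 4 of 100 draws gave as many, with a highest other of 3280. That is a structure of the samples, since the other 3 all kept the METTL3 groups intact, of 6 such draws, while draws that broke those groups gave at most 1 gene.

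A liver far from the other 3 of its group appeared in 36 of 396 groups checked, where chance gives about 1 in 20 (19.8 expected), and in 16 of the 36 it was a replicate 4 knockout. Among library measures these were the TMM factor (1.16) and brain list (1983 CPM) of the liver labelled RPN11 knockout 4, the total (15980959 counts) and brain list (1719.7 CPM) of METTL3 knockout 4, and the share of the top 10 genes in METTL3 knockout 1 (22.3%).

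In labelled RPN11 knockout 4 the outlying levels were Gpr22 9.75, Ptprn 10.9, Gpr141 5.98, Bcl2a1d 9.18, Sirpb1c 5.12, Klhl11 5.90, Sla 13.5, Acsl5 263, Ifi27 110.2 and Ptprc 55.8 CPM. Outlying elsewhere in that line were Tat 2872 CPM in labelled knockout 2, Bckdha 64.6 CPM in labelled knockout 3, Vnn1 103.9 CPM in flox/flox 2 and Fbxo2 0.041 CPM in flox/flox 3. In METTL3 knockout 1 they were Gldn 7.65, Dhrs9 12.0, Rsad2 13.7, Mgll 90.5 and Abcc4 5.69 CPM. Other METTL3 knockouts gave Acss3 8.13 CPM in liver 2 and Cyp17a1 6.14 and Spp1 531 CPM in liver 4. Among METTL3 flox/flox livers, number 3 gave Tuba8 1.12, Rnf213 62.0, Fads2 464, Bphl 163, Plin4 14.6 and Lect2 233 CPM, number 2 Lmod2 0.82 and Cyp51 126 CPM, and number 1 Vmn2r3 0.041 CPM.

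A different effect in the lines, by the interaction contrast, was found for 1720 genes, for 91 of the named genes and for the circadian clock list (median log2 difference 1.10, adjusted p = 0.000419 with an estimated correlation). The values below are log2 effects of the RPN11 line minus the METTL3 line, all with adjusted p under 0.05, and they rest on the label of the RPN11 knockouts. Clock genes gave Usp2 4.84, Per3 2.43, Tef 1.895 and Dbp 3.66. Glucose and amino acid genes gave Pfkfb1 1.96, Asl 2.56, Slc37a4 1.70, Pfkfb3 3.32, Sds 2.78 and Ass1 1.57. They also gave Arg1 1.32, Tat 1.48, Oat 1.997, Shmt2 0.83, Gulo 1.19 and Tkt -0.96. Fatty acid and lipid genes gave Lpin1 3.24, Acsl3 -1.56, Plin4 3.28, Mgll 0.99, Srebf1 -1.18, Apoc3 1.34 and Acsl4 -1.89. They also gave Fasn -1.50, Acsl5 -0.76, Acadl 0.75, Mid1ip1 -0.92, Slc25a20 0.82 and Mfsd2a 5.45. Sterol and bile acid genes gave Cyp7a1 2.33, Fdft1 -1.38, Cyp51 -1.05, Idi1 -1.44, Nr1h4 0.81 and Ebp 0.72. Proteasome, heat shock and N6-methyladenosine genes gave Psmb4 0.96, Psmd4 0.84, Psmb2 0.72, Psmb1 0.63 and Psma1 0.66. They also gave Hspb8 1.30, Dnaja1 0.95, Mettl3 1.60, Hnrnpa2b1 0.97 and Ythdf2 -0.80. Interferon, macrophage and inflammatory genes gave Ifi27 1.92, Oasl1 -2.18, Usp18 1.28, Icam1 -1.29, Vsig4 -1.32, C1qc -0.84, Cd5l -1.46 and S100a9 -3.01. Matrix and stellate genes gave Fbn1 -2.39, Col6a3 -1.53, Col1a1 -2.31, Lum -0.89, Lrat -1.47 and Pdgfrb -1.13. Growth, fetal liver and biliary genes gave Ccnd1 -2.21, Sox9 -1.62, Mcm6 -2.25, Golm1 -2.58 and Elf3 -5.22. Hepatocyte secretory, drug-handling and regulatory genes gave Por 1.79, Cyp3a11 -1.78, Gstm3 -4.09, Rbp4 1.59, Cebpa 0.89, Cebpb 1.37 and Lect2 1.13. They also gave Nr1i3 2.25, Abcc4 -3.09, Itih4 -1.03, Selenbp2 3.17, Cyp17a1 3.42 and Aqp8 -1.25. Other named genes gave Cdip1 1.69, Dhrs9 -4.53, Mtss1 1.62, Coq10b 2.20, Rrnad1 1.53 and St6gal1 -2.80. They also gave Lmod2 4.90, Pcp4l1 3.02, Sema5b 2.36, Dclk3 -0.82 and Fam73b 0.64. Fitted values that depend on the prior added to near-zero counts were 7.97 for Fbxo2, -7.38 for Tmc5 and -7.30 for Vmn2r3.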

How the results depend on the processing

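Leaving out both replicate 4 knockouts was the only alternative among these tests that was chosen after the results were seen. No named gene reversed its direction past the threshold, and of the values of named genes over all alternatives 5314 stayed on their side, 139 became past it and 458 were no longer past it, 357 of these with 1 liver left out. Changes of the counts follow in part from fewer livers or other sets of tested genes by construction, and otherwise the cause was not tested. Alternatives in the pseudocount were not run, since the values are counts. Depth limits genes with few counts, such as Fbxo2, Tmc5, Vmn2r3 and Gldn.

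In the RPN11 line the counts of higher and lower genes (241 and 342) were 149 and 201 with no filter, 592 and 741 with DESeq2, 649 and 809 with voom and quality weights, 160 and 183 in 1 fit of all 16 livers and 78 and 45 with a 2-fold threshold. Higher genes were 377 with a mean of at least 5 CPM and 447 without both replicate 4 knockouts, while lower genes stayed within 1.5 times in these. With 1 liver left out they ran from 37 to 447 and from 18 to 494, as given above.

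In the METTL3 line the counts (1893 and 1906) stayed within 1.5 times in all but the 2-fold threshold (1068 and 668). The difference between the effects (1720) was 3478 with voom and 942 with a 2-fold threshold, and ran from 1095 (without RPN11 flox/flox 1) to 2663 (without METTL3 knockout 1), with 1110 without labelled RPN11 knockout 2.

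Genes between the flox/flox groups (38) were 66 with RLE, 144 with no filter, 83 with a mean of at least 5 CPM, 412 with DESeq2, 174 with voom and 12 with a 2-fold threshold. With 1 liver left out they ran from 1 to 282, as given above.

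Genes higher and lower in both lines (68 and 152) were 44 and 79 with no filter, 205 and 331 with DESeq2, 214 and 413 with voom and 24 and 21 with a 2-fold threshold. Higher genes were 106 with a mean of at least 5 CPM, and lower genes 76 in 1 fit of all livers. With 1 liver left out they ran from 17 to 114 and from 3 to 200. Besides those given above they were 31 and 40 without labelled RPN11 knockout 2, 114 higher without labelled RPN11 knockout 4, and 67 and 99 lower without RPN11 flox/flox 2 and labelled RPN11 knockout 3.

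With the replicate number as a block, 150 and 226 genes were called in the RPN11 line, 7 between flox/flox groups, and 43 higher and 93 lower in both lines, and 20 lists passed in the RPN11 line and 28 in the METTL3 line. Psmd14 in the RPN11 line ran from -0.08 to 0.08 and Mettl3 in the METTL3 line from -1.36 to -1.23 with 1 liver left out, each on its side of the threshold. Lists past the threshold ran from 17 to 22 of 37 in the RPN11 line and from 26 to 29 of 38 in the METTL3 line. With fry 6 lists passed in the RPN11 line and 32 in the METTL3 line.

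Of the 70 calls of largest changes and list examples in the RPN11 line, 28 ended in 1 fit of all 16 livers (highest adjusted p 0.291), 20 with the replicate block, 18 with no filter, 2 each with RLE, DESeq2 and voom and 1 with a mean of at least 5 CPM. Hnrnpa2b1 was lost in 10 of 16 alternatives and Ythdc1 in 7. In the METTL3 line the call of Spp1 ended in 1 fit of all livers (adjusted p = 0.0832) and without flox/flox 1, 3 or 4 (adjusted p = 0.0532, 0.0571 and 0.0532), and with voom those of Acss3, Cib3, Cyp2b9, Elf3 and Moxd1 ended.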

Other observations

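Tests of this part, which are the gene lists not described above, were planned, except those without replicate 4 of the knockout, which were chosen only after the result was seen, and no explanation of them was tested. In the livers labelled RPN11 knockout, a label that Psmd14 did not bear out, few members of these lists were called. For the integrated stress response, of 22 tested members, 3 were higher, 0 lower and 19 not past the threshold. On adjustment within the list alone, 9 were higher and 3 lower (camera adjusted p = 0.0144, adjusted p = 0.430 with an estimated correlation), and without replicate 4 of the knockout 6 higher members were called. Nupr1 (ENSMUSG00000030717) was 3.36-fold higher (5.21 ± 1.61 against 1.55 ± 0.655 CPM, log2 fold change 1.75, SE 0.41, adjusted p = 0.0348), and Ddit3 (ENSMUSG00000025408) 1.68-fold and Cebpb (ENSMUSG00000056501) 1.57-fold higher (adjusted p = 0.0351 and 0.0449). Heat shock and proteotoxic stress passed camera as higher with the preset correlation only (1 higher and 1 lower of 22, 7 and 1 adjusted over the list alone, camera adjusted p = 0.0150, adjusted p = 0.430 with an estimated correlation), with the chaperone gene Hspa1b (ENSMUSG00000090877) 1.74-fold higher (adjusted p = 0.0260) and Nfe2l1 (ENSMUSG00000038615), the transcription factor gene of the proteasome bounce-back response, 1.52-fold lower (adjusted p = 0.0469). Without replicate 4, 7 higher and 1 lower heat shock genes were called. Targets of p53 passed in the same way (2 higher and 0 lower of 24, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0227, adjusted p = 0.430 with an estimated correlation), with Mdm2 (ENSMUSG00000020184) 1.36-fold and Trp53inp1 (ENSMUSG00000028211) 1.64-fold higher (adjusted p = 0.0301 and 0.0175), and did not pass without replicate 4 (adjusted p = 0.1002). Gluconeogenesis and glycolysis passed as lower (2 higher and 3 lower of 22, 2 and 7 adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.474 with an estimated correlation), with Pcx (ENSMUSG00000024892) and Khk (ENSMUSG00000029162) 1.75-fold and 1.77-fold lower and Pfkfb3 (ENSMUSG00000026773) 3.98-fold higher (adjusted p = 0.0317, 0.0180 and 0.00760), and did not pass without replicate 4 (adjusted p = 0.130).

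Xenobiotic metabolism (0 higher and 2 lower of 24, 0 and 4 adjusted over the list alone, camera adjusted p = 0.00114, adjusted p = 0.430 with an estimated correlation), hepatocyte secretory genes (0 higher and 1 lower of 26, 0 and 1 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.430 with an estimated correlation) and pericentral genes (0 higher and 1 lower of 15, 0 and 1 adjusted over the list alone, camera adjusted p = 0.00520, adjusted p = 0.430 with an estimated correlation) also passed as lower, with few members called, among them the receptor gene Nr1i3 (ENSMUSG00000005677) 1.76-fold and Itih4 (ENSMUSG00000021922) 2.20-fold lower (adjusted p = 0.0195 and 0.0288). Without replicate 4 the xenobiotic list (2 higher and 3 lower) and the pericentral list did not pass (adjusted p = 0.0540 and 0.0540), while the secretory list did (adjusted p = 0.0389). NRF2 targets (2 higher and 2 lower of 24, camera adjusted p = 0.763) and clock genes (1 and 2 of 18, adjusted p = 0.177) did not pass. Both had a negative median and a positive mean log2 fold change (-0.13 and 0.22, -0.09 and 0.11). Gstp1 (ENSMUSG00000060803) was 2.16-fold higher (adjusted p = 0.00681), and Clock (ENSMUSG00000029238) was higher and Tef and Per3 lower (log2 fold change 0.51, -0.56 and -0.85, adjusted p = 0.0222, 0.0152 and 0.0230). No member was called in the cell cycle, urea cycle, endothelial, bile acid, stellate, periportal, acute phase, mitochondrially encoded, endoplasmic reticulum stress, ribosomal protein, cholangiocyte and erythroid lists (camera adjusted p = 0.0959, 0.0959, 0.123, 0.123, 0.381, 0.392, 0.649, 0.672, 0.963, 0.963, 0.963 and 0.963). Of these, endoplasmic reticulum stress, cholangiocyte and erythroid lists had a median, mean and test that differed in sign. Neutrophil, adipocyte and pancreas, and histone lists had fewer than 5 tested members.

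In METTL3 knockouts, these further lists passed with the preset correlation and not with an estimated one. Pericentral genes were lower (0 higher and 10 lower of 15, 0 and 10 adjusted over the list alone, camera adjusted p = 2.64e-05, adjusted p = 0.301 with an estimated correlation), with Gulo (ENSMUSG00000034450) 2.73-fold and Oat (ENSMUSG00000030934) 4.83-fold lower (adjusted p = 0.00231 and 0.00381). Hepatocyte secretory genes passed as lower (0 higher and 11 lower of 26, 1 and 11 adjusted over the list alone, camera adjusted p = 0.00463, adjusted p = 0.444 with an estimated correlation), with Rbp4 (ENSMUSG00000024990) at 1065 ± 456 against 3439 ± 469.9 CPM, log2 fold change -1.69, SE 0.29, adjusted p = 0.00181. So did xenobiotic metabolism (4 higher and 10 lower of 23, 4 and 11 adjusted over the list alone, camera adjusted p = 0.00463, adjusted p = 0.357 with an estimated correlation), while Cyp3a11 (ENSMUSG00000056035) rose 3.69-fold (adjusted p = 0.000364) and Por (ENSMUSG00000005514), the reductase gene that serves all microsomal P450 enzymes, fell 4.34-fold (adjusted p = 0.000176). Cholesterol synthesis passed as higher (8 higher and 1 lower of 23, 10 and 1 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.444 with an estimated correlation), with Idi1 (ENSMUSG00000058258) 2.54-fold higher (adjusted p = 0.00533), the direction opposite to the livers labelled RPN11 knockout. NRF2 targets passed as higher (8 higher and 1 lower of 24, 8 and 1 adjusted over the list alone, camera adjusted p = 0.00964, adjusted p = 0.301 with an estimated correlation), with Gstm3 (ENSMUSG00000004038) 20.5-fold higher (adjusted p = 0.00322), and so did p53 targets (11 higher and 2 lower of 24, 13 and 3 adjusted over the list alone, camera adjusted p = 0.00414, adjusted p = 0.395 with an estimated correlation), the integrated stress response (8 higher and 2 lower of 23, 11 and 2 adjusted over the list alone, camera adjusted p = 0.0310, adjusted p = 0.485 with an estimated correlation) and cholangiocyte markers (3 higher and 0 lower of 16, 3 and 0 adjusted over the list alone, camera adjusted p = 0.00302, adjusted p = 0.301 with an estimated correlation). Heat shock genes passed as lower (0 higher and 7 lower of 23, 0 and 7 adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.444 with an estimated correlation), with Dnaja1 (ENSMUSG00000028410) 1.75-fold lower (adjusted p = 0.00345), and 4 lower heat shock genes were called without replicate 4. Without replicate 4 the integrated stress response did not pass (adjusted p = 0.0575).

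Not past the threshold in METTL3 knockouts were ribosomal protein genes (4 higher and 0 lower of 32, camera adjusted p = 0.0891), female-biased genes (1 and 4 of 13, 0.0891) and periportal genes (3 and 6 of 15, 0.112). The same held for lymphocyte (1 and 0 of 13, 0.139), mitochondrially encoded (0 and 2 of 5, 0.141), endothelial (4 and 1 of 19, 0.217) and endoplasmic reticulum stress genes (3 and 1 of 21, 0.242). Erythroid (0 and 2 of 9, 0.324), male-biased (3 and 2 of 18, 0.876) and acute phase genes (3 and 2 of 21, 0.950) did not pass either. Without replicate 4 the lymphocyte list passed with 15 tested members (adjusted p = 0.0492, adjusted p = 0.230 with an estimated correlation). The acute phase list had a negative median (-0.04) and a positive mean (0.15). Adipocyte and pancreas, and histone lists had fewer than 5 tested members.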
